A study of Arabidopsis thaliana with 9 samples.

How the data were processed

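Whole roots of Arabidopsis thaliana seedlings 7 days after germination were profiled on Affymetrix ATH1 arrays, 1 array per sample, in 3 groups of 3 biological replicates. All plants carried ga1-3, a mutation in the gibberellin (GA) biosynthesis gene GA1. The groups were ga1-3 itself, ga1-3 with scl3-1, a loss-of-function mutation of the GRAS protein gene SCL3, and ga1-3 with SCL3 overexpressed according to the labels (SCL3 OE). Per the labels, seedlings grew on MS medium at 22 °C with 16 h light and 8 h dark, and 300 ng of RNA per sample was amplified and biotin-labelled with a 3' IVT kit. The deposited values are MAS5 signal intensities per probe set on a linear scale, made by the authors with Affymetrix Expression Console 1.1. Each array had been scaled to a common trimmed mean: the 2% trimmed mean was between 496 and 497 on all 9 arrays. No detection calls and no Affymetrix control probe sets were in the table, so the planned checks of 3' to 5' signal, hybridisation controls and poly-A controls were not run.

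Signals were taken to log2 with the deposited scaling kept. Of 22746 probe sets, 14117 were kept because at least 3 arrays lay at or above the 40th percentile of their own array, which corresponded to a signal of 105.9 on average. A group-means model over all 9 arrays was fitted in R 4.3.3 with limma 3.58.1, using eBayes with a mean-variance trend. It had 6 residual and 9.37 prior degrees of freedom. Its contrasts were scl3-1 against ga1-3, SCL3 OE against ga1-3, SCL3 OE against scl3-1, and the mean of both SCL3 lines against ga1-3. All tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all kept probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. Every adjusted p of a gene is from limma, and every error of a log2 change is the standard error (SE) of that model. Group signals are means with the standard deviation (SD) of 3 arrays. The number of arrays limits the precision of every value.

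Gene names came from a probe table and a gene table of the TAIR10.1 assembly, which was used for names and gene order only. The probe table listed 14016 probe sets, 13513 of them with 1 gene (13356 genes) and 503 with several. The other 8730 probe sets are unnamed here, as are 6158 of the kept ones. SCL3 and GA1 were on no named probe set, so their planned values are not given and the labels could not be checked by the manipulated gene. The kept probe sets covered 7621 genes. A gene with several probe sets was represented by the one with the highest mean over all arrays.

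Genes to name were chosen by a rule: among called probe sets with 1 gene, with 3 arrays of one group all above the 3 of the other and the brighter group's mean above the mean array median (192.7), the 10 with the largest rise and the 10 with the largest fall. From each fixed gene list, the 4 members with the smallest p were added, or all members where at most 6 were measured. Genes on probe sets shared by several genes were not named. Of the 40 lists fixed in advance, holding 465 genes, 62 genes were measured and 50 tested. For 14 lists no gene was measured, 21 had a tested gene, and the 7 with at least 4 tested genes were tested with camera at its preset inter-gene correlation of 0.01. The same tests were repeated with an estimated correlation and with fry, a rotation test that asks whether the genes of a set move 1 way and compares them with no other genes. The samples, groups, lists, comparisons, rule and alternatives were chosen before the data were examined. Lists of plastid-encoded, mitochondrion-encoded and nuclear-encoded photosynthesis genes, class III peroxidases and extensins, and 18 families of at least 8 tested genes sharing a symbol stem, were added after seeing the data.

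The fold changes of both lines against ga1-3 share the ga1-3 arrays. Their correlation and covariance across probe sets were therefore set beside 1000 simulated data sets with unchanged groups, drawn by rotating the residuals of the model. Grouping of called genes along the chromosomes was counted as called genes with another called gene among the 10 next tested genes. The planned reference, 10000 circular shifts of the calls, could not detect a simulated block of calls (permutation p = 0.963 in the test on simulated data). Random placement of the calls, added after seeing the data, found that block with a permutation p of 1e-04, the smallest it can give.

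Alternatives were no dim filter, a filter at the 60th percentile, quantile normalization, median-centred arrays, an offset of 50 before log2, eBayes without trend, robust eBayes, array weights, a block for replicate number, only the 6 arrays compared, a 2-fold minimum, an adjusted p of 0.1, 1 probe set per gene, windows of 5 and 20 genes, and each array left out in turn. The calling step was tested on simulated data with known changes. Their noise was normal, independent for each probe set and drawn with the model's own variances, so noise shared between probe sets was not tried. The step recovered 46.8% of changes of 0.5 log2, 98.5% of changes of 1 and 100% of changes of 2 in a simulated scl3-1 comparison, with 5 false calls among 163. In a simulated SCL3 OE comparison the shares were 53.6%, 96.9% and 100%, with 9 false calls among 175.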

Results

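The data were 9 arrays of whole roots, 3 each of ga1-3, ga1-3 scl3-1 and ga1-3 SCL3 OE. GA1 encodes ent-copalyl diphosphate synthase, an early enzyme of gibberellin synthesis, and SCL3 is a GRAS protein, a relative of the DELLA repressors of gibberellin signalling. Median signals were 190 to 204 on the ga1-3 and scl3-1 arrays and 183 to 185 on the SCL3 OE arrays. The 99th percentile of signal was higher in SCL3 OE, at 8374 to 9087 against 5846 to 6649 on the other 6 arrays. The brightest 100 probe sets took 9.33% to 10.6% of all signal in SCL3 OE and 6.54% to 7.64% elsewhere.

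Profiles of ga1-3 and scl3-1 resembled each other about as closely as the ga1-3 replicates did. Across kept probe sets, which are not independent replicates, Pearson's r was 0.978 to 0.985 between ga1-3 and scl3-1 arrays, 0.978 to 0.987 within ga1-3, 0.984 to 0.990 within scl3-1 and 0.989 to 0.990 within SCL3 OE. Between SCL3 OE arrays and the others it was 0.929 to 0.945. The first principal component, 66.9% of the variance, separated SCL3 OE from the rest, and the second held 7.86%. The largest fall in scl3-1 among all kept probe sets was on one that the probe table used here does not name, singled out after its values were seen. Its signal was 1228 ± 136 (SD, n = 3) in ga1-3, 22.6 ± 12.2 in scl3-1 and 1254 ± 84.4 in SCL3 OE. The log2 change was -5.97 (SE 0.33, adjusted p = 1.18e-07) in scl3-1 and 0.03 (95% interval -0.66 to 0.73, adjusted p = 0.943) in SCL3 OE. Which gene it measures is not known here, so neither the loss nor the overexpression of SCL3 was checked by signal. Were it SCL3, its signal would not show the overexpression that the SCL3 OE label states.

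Loss of SCL3 in the GA-deficient background was examined by comparing scl3-1 with ga1-3. GIGANTEA (GI, AT1G22770), a circadian clock gene, rose 1.95-fold, from 600 ± 36.0 (SD, n = 3) to 1198 ± 314 (log2 change 0.97, SE 0.16, adjusted p = 0.0164). The neighbouring genes AT4G12490 and AT4G12500, which encode lipid-transfer-like proteins, rose by 0.94 (SE 0.19) and 0.99 (SE 0.20) on the log2 scale. AT5G19890, a class III peroxidase gene, rose from 467 ± 13 to 834 ± 124 (0.83, SE 0.12, adjusted p = 0.0112). The extensin gene AT4G08410, measured by a probe set that may bind related genes, rose by 0.89 (SE 0.16), and the cytochrome P450 gene CYP71B26 rose by 0.73 (SE 0.12). AT1G73600, a phosphoethanolamine methyltransferase gene, and AT3G21670, a nitrate transporter gene, rose by 0.85 (SE 0.15) and 0.71 (SE 0.14). Among the genes that fell, AT4G27450 went from 608 ± 23.9 to 297 ± 89.7 (-1.08, SE 0.18, adjusted p = 0.0205). AT5G35940 fell to 385 ± 56.1 from 711 ± 116 (-0.88, SE 0.14) and AT1G19530 to 238 ± 35.4 from 431 ± 39.5 (-0.86, SE 0.16). The asparaginase gene ASPGB1 fell by 0.67 on the log2 scale (SE 0.14) and IVD, whose enzyme acts in leucine degradation, by 0.54 (SE 0.11). These calls rested on few arrays. All 17 genes chosen by the rule lost their call without ga1-3 replicate 2 (adjusted p 0.0629 to 0.199) or without scl3-1 replicate 2 (0.0833 to 0.186). Without ga1-3 replicate 3 it was 14 of them (0.0573 to 0.176), without scl3-1 replicate 1 it was 11 (0.0563 to 0.117) and without scl3-1 replicate 3 it was 7 (0.0607 to 0.141). Leaving out SCL3 OE replicates 1, 2 and 3, which enter through the shared spread, ended 7 (0.0524 to 0.0795), 3 (0.0581 to 0.0771) and 9 calls (0.0535 to 0.0715), and leaving out ga1-3 replicate 1 ended 1 (0.0535). By eBayes without trend, only AT5G19890, AT5G35940 and AT1G19530 of the genes named here kept the call (others 0.0512 to 0.111). Without a dim filter it ended for AT4G12490, AT4G12500, AT4G08410, AT1G73600, AT3G21670, AT1G19530, ASPGB1 and IVD (0.0558 to 0.101), and with only the 6 arrays compared for AT4G12490, AT4G12500, AT1G73600, AT3G21670, ASPGB1 and IVD (0.0531 to 0.115). With a replicate block it ended for AT4G12500 (0.0653), ASPGB1 (0.0568) and IVD (0.052), and for ASPGB1 also after quantile normalization (0.0714) and in robust eBayes (0.0501).

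In all, 76 of 14117 probe sets changed in scl3-1, 52 up and 24 down, and 13 of them changed at least 2-fold. With median-centred arrays 42 rose and 29 fell, so the share that rose was 59.2% in place of 68.4%. Of the 76, 30 named 1 gene and 45 were unnamed here. Among the 30, the largest rises were those of AT3G05170 (2.51, SE 0.245, adjusted p = 0.000203) and AT2G16890 (1.77, SE 0.283, adjusted p = 0.0164). These 2 genes lay outside the naming rule in scl3-1 and were also called as higher in SCL3 OE. AT3G05170 had signals of 10.8 to 20.7 in ga1-3 and 80.2 to 98 in scl3-1, below the filter level of 105.9, so its size is uncertain. The largest changes of unnamed probe sets, besides the fall above, were a rise from 139 to 425 (log2 change 1.65, SE 0.23) and a fall from 883 to 299 (-1.71, SE 0.32). A further one rose by 2.03 (SE 0.38), but from 8.15 to 31.6, with both means far below the filter level of 105.9. At an unadjusted p under 0.05 there were 1506 probe sets. The 3 arrays of one group all lay above the 3 of the other for 1984 probe sets (14.05%), where chance gives 10%. The count was 148 without ga1-3 replicate 1, 5 without ga1-3 replicate 2, 15 without ga1-3 replicate 3, 23 without scl3-1 replicate 1, 3 without scl3-1 replicate 2 and 43 without SCL3 OE replicate 3.

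Of the genes in the 7 tested lists, limma called 0 in scl3-1, over all genes or adjusted over the list alone. GID1A, GID1B and GID1C, the gibberellin receptor genes, changed by 0.06 (SE 0.11), 0.07 (SE 0.11) and -0.18 (SE 0.17) and did not pass. Xyloglucan endotransglucosylases had the lowest list p, with a mean of 0.21 and an adjusted p of 0.179 (camera). That list passed without ga1-3 replicate 1 (0.35, adjusted p = 0.00603). For the list of genes linked to SHR and SCR, the mean of -0.10 did not pass in camera (adjusted p = 0.583, and 0.637 with an estimated correlation). Fry gave an adjusted p of 0.0207. Among smaller lists, the cortex marker AT1G09750 rose when adjusted over the list alone (0.26, SE 0.10), but not over all genes (adjusted p = 0.312). The pyruvate decarboxylase gene PDC2 did likewise (0.53, SE 0.13, adjusted p = 0.0873), and it passed over all genes without scl3-1 replicate 3 (0.65, adjusted p = 0.043).

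The line labelled as overexpressing SCL3 was compared with ga1-3. AT3G12900, which encodes scopoletin hydroxylase, an enzyme of coumarin synthesis under iron deficiency, rose from 18 ± 12 (SD, n = 3) to 259 ± 31.2 (log2 change 4.07, SE 0.39, adjusted p = 1.22e-06). MSRB6, a methionine sulfoxide reductase gene, rose from 207 ± 57.1 to 1690 ± 249 (3.06, SE 0.17). AT3G05170 and AT3G56290, which were also called as higher in scl3-1, rose by 3.88 (SE 0.24) and 3.69 (SE 0.22). The hydroxycinnamate glucosyltransferase gene UGT84A1 rose by 3.09 (SE 0.42) and the lipase gene AT5G37690 by 2.25 (SE 0.12). The plastid-encoded accD, a subunit gene of acetyl-CoA carboxylase, rose by 2.22 (SE 0.19). XTH26, a xyloglucan endotransglucosylase gene of root hairs, fell from 362 ± 64.8 to 24.8 ± 10.1 (-3.94, SE 0.24, adjusted p = 1.6e-08). The class III peroxidase gene AT1G34510 went from 969 ± 105 to 68.8 ± 8.99 (-3.82, SE 0.13) and the sucrose transporter gene SWEET11 from 1079 ± 118 to 134 ± 25.5 (-3.02, SE 0.15). AT1G19530 fell by 2.78 on the log2 scale (SE 0.16) and AT1G30760, a berberine-bridge-enzyme-like gene, by 2.40 (SE 0.15). COR27, a cold and clock gene, changed by -2.28 (SE 0.25) and its homologue AT4G33980 by -2.09 (SE 0.14). GI also fell (-1.16, SE 0.16, adjusted p = 2.83e-05). The ga1-3 signal of AT3G12900 and the SCL3 OE signal of XTH26 lay far below the filter level of 105.9, so the sizes of these changes are uncertain. With an offset of 50 before log2 AT3G12900 rose 4.6-fold, XTH26 changed by -2.46 on the log2 scale, AT3G05170 and UGT84A1 changed by 2.09 and 2.03, and COR27 fell 2.84-fold. The calls of the 20 genes chosen for their size held without any 1 array.

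**Figure D1:**
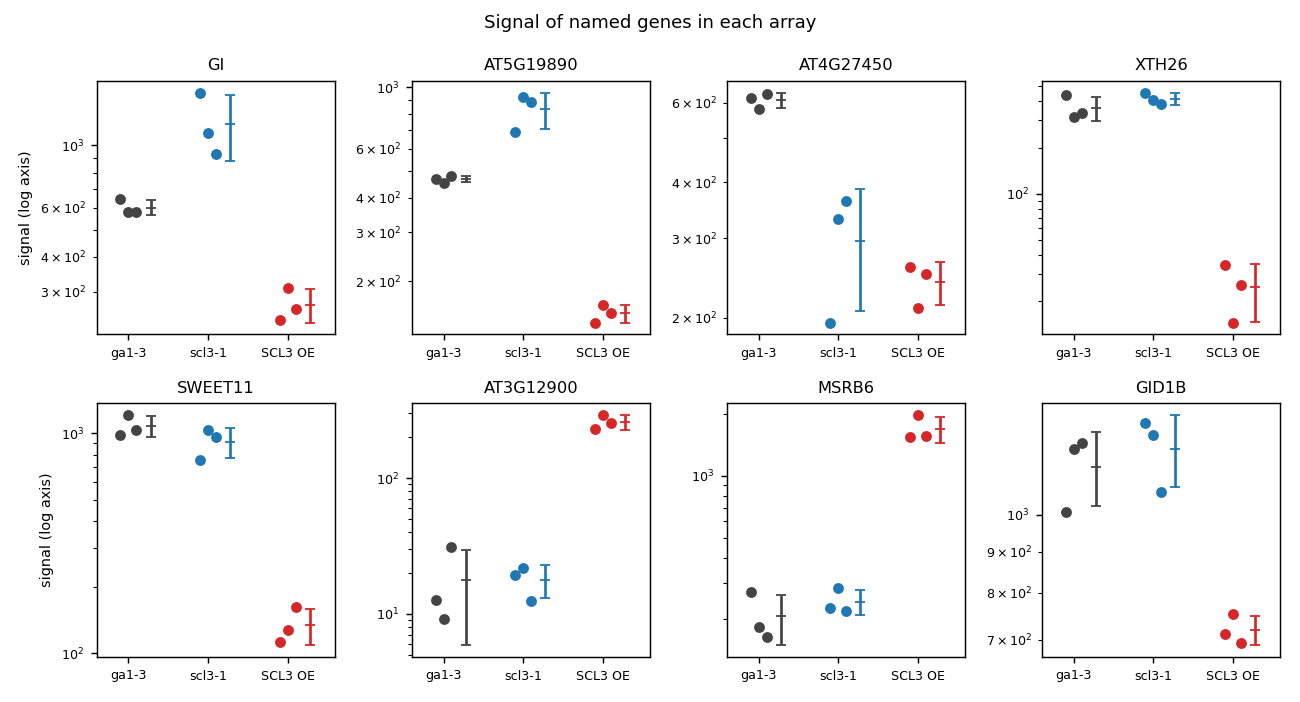
Signal of 8 genes on a log axis for each array (points), with the mean and SD of the 3 arrays per group (bars), in ga1-3, scl3-1 and SCL3 OE. XTH26 went from 362 in ga1-3 to 24.8 in SCL3 OE and AT3G12900 from 18 to 259, while GI was 600, 1198 and 269 in the 3 groups.

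Most tested genes of gibberellin perception and DELLA degradation were lower in SCL3 OE. Of 11 listed, 6 were on named probe sets, and of these 5 fell and 0 rose, the same when adjusted over the list alone. SLY2 and SLY1 encode F-box proteins that target DELLAs for degradation, and they fell by 1.27 (SE 0.20; by 0.83 with an offset of 50) and 0.39 (SE 0.09) on the log2 scale. The receptor gene GID1B went from 1147 ± 121 (SD, n = 3) to 719 ± 30.3 (-0.67, SE 0.11, adjusted p = 0.000152) and GID1A fell by 0.61 (SE 0.11), whereas GID1C did not pass (-0.03, SE 0.17). SPY, an O-fucosyltransferase gene that restrains gibberellin signalling, fell by 0.38 (SE 0.13, adjusted p = 0.0238), but did not pass after quantile normalization (0.135) or median-centring (0.06), nor without ga1-3 replicate 3 (0.0942), SCL3 OE replicate 1 (0.082) or SCL3 OE replicate 2 (0.0661). The list's mean was -0.56 with an adjusted p of 0.0275 (camera), and adjusted p = 0.0973 with an estimated correlation. Of 4 early genes activated by DELLAs, 3 fell and the RING-H2 gene XERICO did not pass (-0.11, SE 0.11), with the same count adjusted over the list alone. The third faller besides GID1A and GID1B was the bHLH gene AT2G31730 (-1.46, SE 0.29). That list's mean was -0.71 with an adjusted p of 0.0559 (camera). It passed without ga1-3 replicate 3 (0.0455), scl3-1 replicate 1 (0.0331), scl3-1 replicate 3 (0.0487) or SCL3 OE replicate 1 (0.0432), and in fry (0.00143). With an estimated correlation it did not pass (camera adjusted p = 0.181). A pass in fry is weak evidence in SCL3 OE, since some families sharing only a symbol stem passed it too.

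JKD, a zinc finger gene of ground tissue patterning, fell in SCL3 OE (-1.23, SE 0.18, adjusted p = 6.92e-05), as did the GRAS gene AT5G41920 (-0.67, SE 0.17; -0.44 with an offset of 50). They belong to a list of 4 tested genes linked to SHR and SCR, of which 3 fell, also when adjusted over the list alone. The third was SLY2, which the list shares with gibberellin perception. The co-regulator gene SEU did not pass (0.22, SE 0.13), but rose after quantile normalization (0.34, adjusted p = 0.0375). The list's mean was -0.74 and did not pass in camera (adjusted p = 0.134, and 0.198 with an estimated correlation), while fry gave an adjusted p of 4.93e-06. Some families sharing only a symbol stem also passed fry in SCL3 OE. Both measured cortex markers fell, as they did adjusted over the list alone. AT1G09750 went from 1383 ± 71.5 (SD, n = 3) to 629 ± 5.61 (-1.14, SE 0.10), and AT1G62500 fell by 0.63 (SE 0.20), a call that ended without ga1-3 replicate 1 (adjusted p = 0.0802) or SCL3 OE replicate 2 (0.0745). GSO1, a receptor kinase gene of the Casparian strip and the only tested gene of the endodermis list, did not pass over all genes (0.31, SE 0.15, adjusted p = 0.0958). It rose when tested over the list alone, after quantile normalization (0.44, adjusted p = 0.032) and with median-centred arrays (0.39, adjusted p = 0.0434).

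All 4 root hair genes on named probe sets, of 18 listed, fell in SCL3 OE, also adjusted over the list alone. Their median was -0.73, and their mean of -1.44 rests largely on XTH26. Beside XTH26, these were the root hair expansin genes EXPA18 (-0.91, SE 0.09) and EXPA7 (-0.37, SE 0.12) and the peroxidase gene AT1G30870 (-0.55, SE 0.09). EXPA7 did not pass after quantile normalization (adjusted p = 0.103), nor without ga1-3 replicate 1 (0.0942), SCL3 OE replicate 1 (0.0685) or SCL3 OE replicate 2 (0.0555). The list gave an adjusted p of 0.00374 in camera, and adjusted p = 0.0686 with an estimated correlation. Of 14 listed genes of the iron deficiency response, 4 were on named probe sets. Of these 4, 3 rose, the same adjusted over the list alone, with a median of 1.08 and a mean of 1.59 that rests largely on AT3G12900. Beside AT3G12900, the bHLH gene BHLH101 rose from 79.4 ± 20.6 (SD, n = 3) to 212 ± 23.3 (1.44, SE 0.23) and the feruloyl-CoA hydroxylase gene AT3G13610 rose by 0.72 (SE 0.13; by 0.44 after quantile normalization), while PYE did not pass (0.13, SE 0.12). This list too gave an adjusted p of 0.00374 in camera, and adjusted p = 0.0686 with an estimated correlation.

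**Figure D2:**
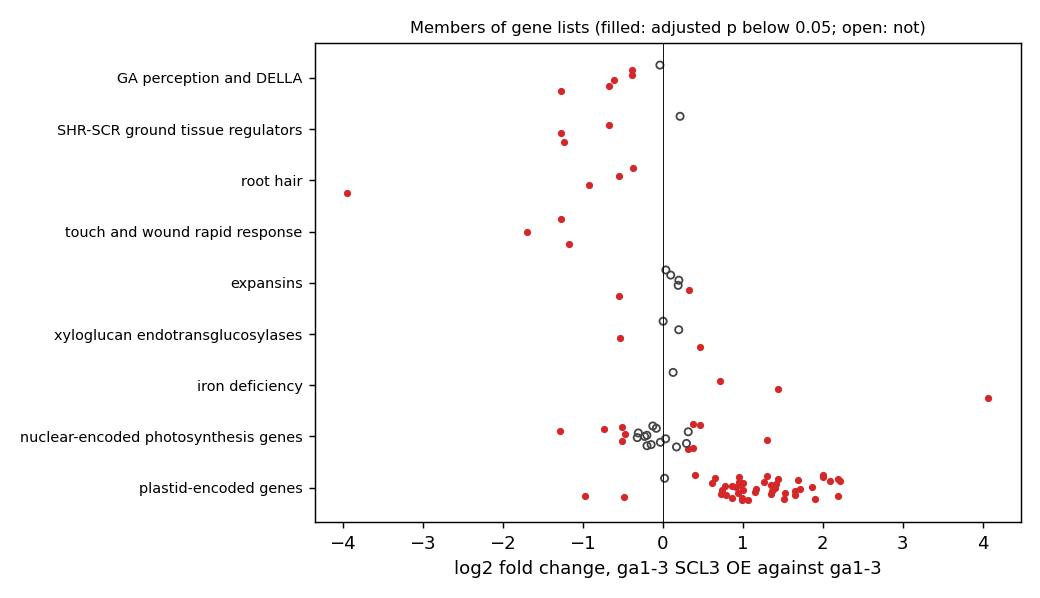
Log2 change in SCL3 OE against ga1-3 of each tested member of selected gene lists, filled where the adjusted p was under 0.05. The lists of plastid-encoded and nuclear-encoded photosynthesis genes were added after seeing the data. The others are part of the lists fixed in advance. Root hair genes lay below 0, down to -3.94 for XTH26, and iron deficiency genes above 0, up to 4.07 for AT3G12900.

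Other lists held few measured genes or moved both ways. All 3 measured genes of rapid touch and wound responses fell, the same adjusted over the list alone: WRKY53 (-1.70, SE 0.22), the calmodulin-like gene CML37 (-1.27, SE 0.25; -0.79 with an offset of 50) and the zinc finger gene STZ (-1.17, SE 0.08). The dehydrin gene LTI30 rose by 0.99 (SE 0.11), or by 0.44 after quantile normalization, and the auxin-conjugating gene GH3.3 by 0.83 (SE 0.15). The ethylene-signalling gene RTE1 fell by 0.98 on the log2 scale (SE 0.11) and the glucosinolate gene BCAT4 by 1.09 (SE 0.15). The lists of expansins and xyloglucan endotransglucosylases held part of each family, without the root hair genes EXPA7, EXPA18 and XTH26. Of 6 expansins in the list, EXPB3 rose (0.33, SE 0.12), EXPA8 fell (-0.55, SE 0.13) and 4 did not pass, and of 4 listed xyloglucan endotransglucosylases XTH21 rose (0.47, SE 0.15), XTH18 fell (-0.54, SE 0.18) and 2 did not pass. Among all 8 tested genes with an XTH symbol, a family added after seeing the data, 4 rose and 2 fell. These counts were the same adjusted over the list alone, and neither list shifted (camera adjusted p 0.335 and 0.464). XTH18 did not pass after quantile normalization (adjusted p = 0.0843) or with array weights (0.0501), nor EXPB3 by eBayes without trend (0.0515). The aurora kinase genes AUR1 (-0.27, SE 0.10) and AUR2 (-0.47, SE 0.17) fell, but passed under neither of the other scalings. SIM, a cell cycle inhibitor gene, rose (0.39, SE 0.11), though not after quantile normalization (adjusted p = 0.056). PDC2 rose by 0.36 (SE 0.13), though not by eBayes without trend (adjusted p = 0.0556). RCA, the rubisco activase gene, rose by 0.32 (SE 0.10), whereas LHCB4.1, a light-harvesting gene, fell by 0.51 on the log2 scale (SE 0.12). Of 53 named genes called in this comparison, including those of the lists above, 8 lost the call without ga1-3 replicate 1 (adjusted p 0.0542 to 0.125), 4 without replicate 2 (0.0738 to 0.0915) and 3 without replicate 3 (0.0632 to 0.0942). Without SCL3 OE replicates 1, 2 and 3 it was 7 (0.0514 to 0.106), 8 (0.0555 to 0.19) and 5 (0.0618 to 0.0824). Without scl3-1 replicate 2 or 3, AUR1 alone lost it (0.0561 and 0.0552). Beside SPY, EXPA7 and AT1G62500, the genes concerned were AUR1, AUR2, EXPB3, XTH18, XTH21, RCA and PDC2.

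In all, 6190 probe sets changed in SCL3 OE, 43.9% of those tested, with 2540 up and 3650 down. The change was at least 2-fold for 771, 314 of them up. The 3 arrays of one group all lay above the 3 of the other for 53.6% of probe sets, where chance gives 10%. The balance of directions depended on the scaling: 41.0% of the called probe sets rose with the deposited scaling, 53.4% (3187 of 5965) with median-centred arrays and 48.6% (2650 of 5454) after quantile normalization. After quantile normalization 4720 of the 6190 were still called, 4706 of them in the same direction. Among unnamed probe sets, the largest changes were rises from 8.15 to 304 (5.37, SE 0.38) and from 52.8 to 910 (4.28, SE 0.34) and falls from 126 to 9.09 (-4.43, SE 0.60) and from 688 to 41.8 (-4.06, SE 0.15). Their lower means all lay below the filter level of 105.9, so the sizes are uncertain.

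The direct comparison of SCL3 OE with scl3-1 tests whether the effects of both lines differed, and the ga1-3 arrays enter it only through the shared spread. AT3G12900 was higher in SCL3 OE (log2 difference 3.89, or 2.18 with an offset of 50, SE 0.39, n = 3 per group, limma adjusted p = 2.07e-06) and XTH26 lower (-4.15, SE 0.24, or -2.64 with the offset). MSRB6 was higher by 2.79 (SE 0.17), the carboxypeptidase-like gene scpl31 by 2.84 (SE 0.19) and psaI, a plastid-encoded photosystem I gene, by 1.98 (SE 0.12). AT5G19890 (-2.44, SE 0.12), AT5G39580, a further class III peroxidase gene (-2.41, SE 0.16), and the calmodulin-like genes AT3G01830 (-2.98, SE 0.25) and AT1G76640 (-2.50, SE 0.34) were lower. Of the gibberellin perception genes 4 of 6 were lower, or 5 adjusted over the list alone, with a mean of -0.54 and an adjusted p of 0.029 (camera), and adjusted p = 0.0999 with an estimated correlation. Early DELLA targets had 3 of 4 lower and a mean of -0.76 (0.0345, and adjusted p = 0.144 with an estimated correlation), and did not pass without scl3-1 replicate 2 (0.0577). All 4 measured root hair genes were lower (mean -1.56, adjusted p = 0.00181, and 0.0868 with an estimated correlation). Of 4 iron deficiency genes 3 were higher (mean 1.42, adjusted p = 0.0105, and 0.0999 with an estimated correlation). AT3G13610 among them (0.36, SE 0.13) did not pass after quantile normalization (adjusted p = 0.879), nor without scl3-1 replicate 1 (0.131), scl3-1 replicate 3 (0.0847), SCL3 OE replicate 2 (0.142) or SCL3 OE replicate 3 (0.0794). For these lists other than gibberellin perception, the counts were the same adjusted over the list alone. In all, 5527 probe sets differed, 2189 higher and 3338 lower in SCL3 OE, or 39.6% higher. With median-centred arrays it was 59.0% (3166 of 5369) and after quantile normalization 49.2% (2317 of 4710), and median-centring moved the median of all probe sets from -0.07 to 0.06. Non-overlapping groups made up 52.8% of probe sets, against 10% by chance.

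The mean of both lines against ga1-3 was tested too, but a change in SCL3 OE alone can pass it. Of the genes it called, AT3G56290 rose by 2.44 (SE 0.19, limma adjusted p = 1.4e-06, n = 3 arrays per group) and AT1G73600 by 1.42 (SE 0.13), AT1G19530 (-1.82, SE 0.13) and AT4G27450 (-1.22, SE 0.16) fell, and all 4 were called the same way in each line. Other genes passed in the mean but not in scl3-1 itself: LPR1, a ferroxidase gene of the root response to low phosphate (1.05, SE 0.11), the ubiquitin ligase gene ATL8 (-1.26, SE 0.13), the methionine gamma-lyase gene MGL (-1.14, SE 0.15) and AT1G22330 on its brighter probe set (-1.06, SE 0.14), whose other probe set did not pass in the mean (-0.19, adjusted p = 0.345). In all, 3146 probe sets changed, 1375 up and 1771 down. Of the 52 probe sets that rose in scl3-1, 30 also rose in SCL3 OE, where independence would give 9.36, and 9 fell (13.4). Of the 24 that fell, 14 also fell in SCL3 OE (6.21) and 1 rose (4.32). Independence is not what unchanged lines would give, since both comparisons share the ga1-3 arrays. Over all probe sets the sign was the same in both lines for 61.9%. The shared arrays alone gave 66.6% in 20 simulated sets of unchanged groups with independent noise for each probe set. Those groups held no change in SCL3 OE, where 6190 probe sets were called. They therefore give no reference, over all probe sets or for the called ones. Leaving out 1 array moved these counts with the number called in scl3-1. The counts up in both and down in both were 57 and 35 without ga1-3 replicate 1, 4 and 0 without ga1-3 replicate 2, 8 and 1 without ga1-3 replicate 3, 8 and 2 without scl3-1 replicate 1, and 2 and 0 without scl3-1 replicate 2. They were 20 and 10 without SCL3 OE replicate 1, 21 and 10 without replicate 2, and 14 and 8 without replicate 3. Opposite calls, up in scl3-1 and down in SCL3 OE, numbered 19, 0, 2, 4, 0 and 3 without ga1-3 replicates 1, 2 and 3 and scl3-1 replicates 1, 2 and 3.

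Across probe sets, which are not independent replicates, the fold changes of both lines against ga1-3 had a Pearson r of 0.303 and a Spearman rho of 0.317. Both use the same 3 ga1-3 arrays, which alone gave a mean r of 0.477 in simulated unchanged groups (95% range -0.334 to 0.914). Those groups held no change in SCL3 OE, whose real fold changes had an SD of 0.53 across probe sets, against 0.198 in scl3-1. An r is divided by that spread, so the observed and simulated r cannot be compared. A covariance is not divided by it. The simulated covariances still held no real change in SCL3 OE for the array noise to vary with, so their range may be too narrow. The observed covariance was 0.0317, against a simulated mean of 0.0112 (-0.00384 to 0.0358), and 43 of 1000 simulated sets had one as large. With 3 ga1-3 arrays the controls cannot be divided so that each line has 2 of its own, so part of the excess of 0.0206 may come from the shared arrays.

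**Figure D3:**
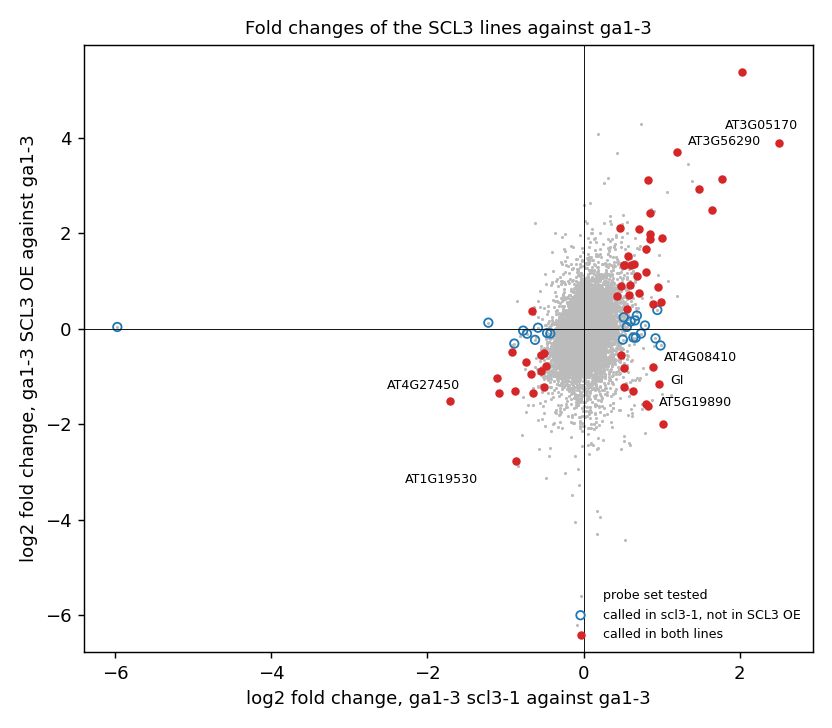
Log2 fold changes against ga1-3 of all kept probe sets in scl3-1 (horizontal axis) and SCL3 OE (vertical axis), 1 point per probe set. The spread was wider along the SCL3 OE axis, and r was 0.303.

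Close grouping of called genes along the chromosomes was not found in scl3-1. Of 30 called genes, 1 had another called gene among the 10 next tested genes (permutation p = 0.686 by random placement among 7556 genes). For the mean of both lines it was 1392 of 1559 (permutation p = 0.896). In SCL3 OE the count was 3116 of 3134 and against scl3-1 2730 of 2757, so near the maximum that grouping could hardly have shown. Of the 20 tested genes nearest to the GA1 locus, 10 per side in the gene order of TAIR10.1, limma called 0 in scl3-1 and 8 in SCL3 OE. Around the SCL3 locus it called 0 and 7 of 20. Of all 7556 ordered genes, 30 were called in scl3-1 and 3134 in SCL3 OE. The counts near both loci are close to these shares and show nothing particular to either locus. Only the 30 called genes could be placed in scl3-1, since 45 of the 76 called probe sets were unnamed here and 1 held several genes. Calls this sparse could hardly show a stretch wider than the windows of 10 and 20 genes. AT3G13650, ASPGB1, AT3G16800, AT3G17130, AT3G21670, AT3G22550 and CYP71B26 lay at places 3514 to 3907 of the 7556 ordered genes, on chromosome 3. This stretch was picked after the calls were seen, and its number of calls was not tested.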

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

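In all, 5 genes were flagged because they were called in opposite ways in the SCL3 lines and limma also called the difference between the lines. That difference nearly followed from how the genes were chosen, so its p is not given. Over all probe sets, 9 rose in scl3-1 and fell in SCL3 OE and 1 did the reverse, where independence would give 13.4 and 4.32. Opposite calls were thus no more frequent than independence would give, though both comparisons share the ga1-3 arrays. GI rose by 0.97 in scl3-1 and changed by -1.16 in SCL3 OE, a difference of -2.13. The peroxidase gene AT5G19890 changed by 0.83 and -1.61 (difference -2.44), and the extensin gene AT4G08410 by 0.89 and -0.79 (difference -1.69). AT2G29340, a short-chain dehydrogenase gene, changed by 0.52 and -0.82 (difference -1.34), and AT3G13650, a dirigent-like gene, by 0.47 and -0.55 (difference -1.02). AT2G29340 and AT3G13650 lay outside the naming rule and were picked after their values were seen. The calls in SCL3 OE held without any 1 array, but those in scl3-1 did not. In the order AT3G13650, AT2G29340, AT5G19890, AT4G08410 and GI, the adjusted p in scl3-1 was 0.12, 0.185, 0.0629, 0.107 and 0.0708 without ga1-3 replicate 2 and 0.145, 0.201, 0.11, 0.139 and 0.0913 without scl3-1 replicate 2. Without ga1-3 replicate 3 the calls of AT3G13650 (0.0811), AT4G08410 (0.107) and GI (0.0573) ended, and without scl3-1 replicate 3 those of AT3G13650 (0.0617), AT2G29340 (0.0672) and AT4G08410 (0.0607). Without scl3-1 replicate 1 it was AT3G13650 (0.0563) and AT2G29340 (0.0735), and without SCL3 OE replicate 1 AT3G13650 (0.0505) and AT2G29340 (0.0782). AT2G29340 also lost it without ga1-3 replicate 1 (0.0647), SCL3 OE replicate 2 (0.0715) or SCL3 OE replicate 3 (0.0715).

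The predictions for the tests below were written before the values that decide them were seen. SCL3 OE differed from ga1-3 at 6190 probe sets, and these arrays also had a wider distribution of signals. Against that width as the whole cause, 5454 probe sets were called after quantile normalization, 4720 of them among the 6190. Of 10 splits of the 6 arrays, 1 (the real one) gave as many, and the highest other gave 0. The same held for SCL3 OE against scl3-1 (1 of 10, real 5527, highest other 0) and for scl3-1 against ga1-3 (1 of 10, real 76, highest other 0), and 10 splits are too few for a share under 0.05. An effect of the SCL3 dose was not tested, since SCL3 was on no named probe set, and stays open.

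More called probe sets differed from ga1-3 in the same direction in both SCL3 lines than independence would give, but both comparisons share the ga1-3 arrays. Over all probe sets the same sign was found for 61.9%. The 66.6% of simulated unchanged groups is no reference for it, since those groups held no change in SCL3 OE. The covariance of the fold changes of both lines was 0.0317, and 43 of 1000 simulated sets with unchanged groups had one as large. Chance values of the shared ga1-3 arrays alone may therefore account for that covariance. Against a single ga1-3 array as the source, at least 83.3% of the covariance beyond the simulated mean was kept without any 1 of them (147%, 101% and 83.3% without replicates 1, 2 and 3). Among 100 groupings of the 9 arrays, 3 gave as many probe sets as the mean of both lines (real 3146, highest other 6840), a share under 0.05. The other 2 both set the SCL3 OE arrays against the rest, and the highest with those arrays split was 1. The share thus reflects where the SCL3 OE arrays fell, so it cannot decide on chance for the mean of both lines. Whether loss and gain of SCL3 share targets stays open.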

How the results depend on the processing

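The number of probe sets called in scl3-1, 76, depended most on the processing. It was 36 without a dim filter, 20 by eBayes without trend, 123 with array weights, 30 with only the 6 arrays compared (fewer samples), 13 with a 2-fold minimum, 152 at an adjusted p of 0.1 and 14 with 1 probe set per gene (fewer genes tested). Except where the construction shows it, the cause was not tested. With a 2-fold minimum and with 1 probe set per gene the counts were 771 and 3148 in SCL3 OE (main 6190), 711 and 2760 in SCL3 OE against scl3-1 (5527), and 146 and 1565 for the mean of both lines (3146). All other settings kept these counts within 1.5 times. Leaving out 1 array gave 3 to 148 in scl3-1, 5015 to 6426 in SCL3 OE, 4320 to 5930 in SCL3 OE against scl3-1 and 2228 to 3094 for both lines. Of 21 list tests 7 passed in camera, 0 with an estimated correlation, 11 in fry and 6 to 8 without 1 array. The correlation of both lines was 0.25 to 0.369 without 1 array (0.303 with all). With windows of 5 and 20 genes, random placement gave a permutation p of 0.437 and 0.376 in scl3-1 and 0.35 and 0.557 for both lines. Circular shifts, and SCL3 OE counts near their maximum, could show little.

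With a replicate block the counts were 73, 6175, 5486 and 3117, with 7 lists and a correlation of 0.303. The replicate numbers did not pair the arrays: with group means removed, r between arrays of the same number was -0.19 to 0.177, and in 7 of 18 pairings with another group an array correlated best with its own number. Class III peroxidases, a list added after seeing the data, had a camera direction of up that did not pass (adjusted p 0.827 in SCL3 OE, 0.913 against scl3-1), although their means were -0.21 and -0.24. Fry gave down for both (adjusted p 0.0135 and 0.00371), as did camera after quantile normalization against scl3-1 (mean -0.30, adjusted p = 0.0432), and the cause was not tested. Among 272 values of named genes, those called in the main analysis kept their sign in every setting, while values near 0 could change it. Of the 272, 21 lost and 2 gained the call by eBayes without trend, 20 and 0 without a dim filter, 12 and 4 after quantile normalization, 8 and 5 with median-centred arrays, 4 and 6 with array weights, 5 and 3 with a replicate block, 1 and 0 in robust eBayes and 0 and 0 with the offset. With only the 6 arrays compared it was 11 and 2 of 202, and at the 60th percentile 0 and 1 of 208. The alternatives for the log2 change of SCL3 were not run, because no named probe set measured it. Signal over background limits the dim genes: no detection calls were given, and changes under the filter level of 105.9 are uncertain.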

Other observations

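Genes of the plastid genome were higher in SCL3 OE roots. This list and those of the next paragraph were chosen after the values were seen, and the nuclear and mitochondrial lists were added for comparison. Of 46 tested plastid-encoded genes 43 rose, 2 fell and 1 did not pass, with a mean of 1.18 and a median of 1.16 (camera adjusted p = 1.9e-26, and adjusted p = 0.00294 with an estimated correlation). psaI, of photosystem I, went from 212 to 906 (log2 change 2.09, SE 0.12, n = 3 arrays per group), and atpA, of ATP synthase, rose by 2.00 (SE 0.20). The maturase gene matK rose by 2.00 (SE 0.19), the RNA polymerase genes rpoC1 and rpoA by 1.87 (SE 0.21) and 1.53 (SE 0.14), the ribosomal protein genes rps15 and rpl32 by 1.91 (SE 0.26) and 1.51 (SE 0.17), and the photosystem II gene psbA by 1.31 (SE 0.22). The fallers were psbE (-0.97, SE 0.11) and psbF (-0.48, SE 0.09). In scl3-1 limma called 0 of these genes, at a mean of 0.14 (camera adjusted p = 0.000577, and adjusted p = 0.157 with an estimated correlation). Of 3 tested mitochondrion-encoded genes, nad4 (1.15, SE 0.15) and cox1 (0.80, SE 0.22) rose and ccb382 did not pass (0.34, SE 0.14, adjusted p = 0.0702), though all 3 rose adjusted over the list alone and under both other scalings. Of 23 nuclear-encoded photosynthesis genes 5 rose and 5 fell, among the fallers PIFI (-1.28, SE 0.25), and their mean of -0.06 turned to 0.04 after quantile normalization and 0.02 with median-centred arrays. The risers among them were 2 without SCL3 OE replicate 1, 3 without replicate 2 and 2 without replicate 3.

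Extensin and class III peroxidase genes changed singly in SCL3 OE, while the lists did not pass in camera against ga1-3. Of 7 tested extensin genes 5 fell, among them AT3G54580 (-1.02, SE 0.26) and AT5G06630 (-0.73, SE 0.11), and AT2G43150 rose (0.81, SE 0.17), with a mean of -0.44 that did not pass (camera adjusted p = 0.183). In scl3-1 their mean was 0.53 (camera adjusted p = 2.42e-08, but adjusted p = 0.105 with an estimated correlation), and AT4G08410 alone was called, or 4 genes adjusted over the list alone. In SCL3 OE against scl3-1 6 of the 7 were lower and 1 higher, with a mean of -0.97 (camera adjusted p = 0.00184, but adjusted p = 0.292 with an estimated correlation). The higher one was no longer called without scl3-1 replicate 1, scl3-1 replicate 3, SCL3 OE replicate 2 or SCL3 OE replicate 3 (0 each). HRGP1, AT5G06630, AT4G08410 and AT1G23720 lie on probe sets that may bind related genes. The number called in scl3-1 was 3 without ga1-3 replicate 1 and 0 without ga1-3 replicate 2, ga1-3 replicate 3, scl3-1 replicate 2 or scl3-1 replicate 3. Of 38 tested peroxidase genes 14 rose and 15 fell in SCL3 OE (camera adjusted p = 0.827, and adjusted p = 0.0135 in fry at a mean of -0.21). The largest falls after AT1G34510 were those of AT5G39580 (-2.05, SE 0.16), AT5G64110 (-1.91, SE 0.16) and AT5G19890 (-1.61, SE 0.12). After quantile normalization 9 peroxidase genes rose and 15 fell. Of 18 families sharing a symbol stem, 0 shifted in camera (lowest adjusted p 0.146), though 8 of 9 PRA genes fell in SCL3 OE against ga1-3 (mean -0.36) and 3 of 9 were lower against scl3-1. In fry, the BGLU, BZIP, GH, GSTU, PRA, SCPL, TET and VPS families passed in SCL3 OE against ga1-3 (adjusted p 0.00278 to 0.0447), and the other families did not. Fry compares a set with no other genes, and 43.9% of probe sets were called in that comparison.

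The rise of plastid-encoded genes in SCL3 OE was set against technical causes. Against shoot tissue or greening of the roots, the median of nuclear-encoded photosynthesis genes was -0.123 (95% interval -0.23 to 0.17). The intervals of this paragraph come from 10000 bootstrap draws of a list's genes, which are not independent replicates. They do not measure the spread between arrays. Against the wider signal distribution, the plastid median was 1.23 (0.96 to 1.43) after quantile normalization. The 3 mitochondrion-encoded genes had a median of 0.796 (0.34 to 1.15, which are just their smallest and largest values). Without a dim filter 15 of 16 mitochondrion-encoded genes lay above 0 (median 0.572), as did 64 of 69 plastid-encoded genes (median 1.27). More labelling of organelle RNA in general therefore cannot be told apart from a rise of plastid transcripts. An effect of SCL3 on plastid transcripts was not tested and stays open.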
